A study of Homo sapiens with 22 samples.

How the data were processed

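The series holds total RNA sequencing of human neuroblastoma cell lines, made with a stranded library kit that removes ribosomal RNA. SH-SY5Y cells carried lentiviral shRNAs, selected with puromycin, against the CASC15-003 or CASC15-004 transcript or a scrambled control. They were grown in 10% serum (day 0), treated for 7 days with retinoic acid at a dose given in the labels as 10 mM (day 7), or grown as spheres. KELLY cells received a SOX9 or a control siRNA. Per the submitters' processing notes, TopHat, featureCounts and Subread were used with genome build hg19. The notes give no versions, no order and no annotation release.

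The deposited values are RPKM in 3 tables of 63677 genes, for monolayer, sphere and KELLY libraries. Whole reads were recovered from RPKM and gene length, with library totals estimated from the spacing of the values. All values came within 0.01 of a whole number. For the monolayer and KELLY tables, RPKM recomputed from these reads differed from the deposited RPKM by at most 5.41e-11. In the sphere table the values came out whole only with 10 estimated totals used in rotation from gene to gene, from 25.59 to 62.08 M. Of these, 5 equal the recovered totals of the 5 sphere libraries, and the source of the others is not known. Most values in a library thus rest on a total other than its own. Values of the spheres were therefore recomputed from the recovered reads with each library's own total, and the deposited values serve as an alternative. The libraries held 11.9 to 62.1 M assigned reads. All 37 mitochondrial genes listed had 0 reads. Of the gene identifiers, 52181 matched the reference gene names, 52526 matched any reference table and 11151 were unmatched. The reference annotation (release 29) is on a later genome build than hg19, so it was used for gene type and overlap only and no coordinates are given.

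Libraries were grouped by title. For a pair of sh003 libraries the differentiation tag contradicts the title (sh1 batch 2 at day 7 and sh2 batch 1 at day 0). CYP26A1 matched the titles, and an alternative leaves both out. The sh004 sh2 sphere carries no culture tag and was grouped by title. No library was left out of the main analysis.

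Genes at RPKM 1 or above in 2 or more libraries of a table were kept, 19461 in monolayers and 14711 in spheres. limma 3.58.1 in R 4.3.3 was fitted to log2(RPKM + 0.5) with a mean-variance trend, all groups of a table sharing a spread with 9 residual degrees of freedom in monolayers and 2 in spheres (prior degrees of freedom 2.12 and 4.22). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The control sphere group has 1 library, whose spread was assumed equal to that of the knockdown pairs. The p-values measure only the spread between these libraries, and the libraries of a knockdown group mix shRNAs and batches. Nothing was tested across tables. The KELLY pair has no replicates and was described by log2 ratios of RPKM + 0.5, with 95% exact (Clopper-Pearson) intervals of the read ratio, which like every count-based interval cover counting error only.

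The titles number 3 batches. Deviations from the group mean of control and sh003 day 0 libraries of the same batch correlated at 0.802 to 0.942 across genes. Over all pairs the median was 0.0999 within a batch and -0.0868 between batches, with a lowest value of -0.204 within a batch. All sh004 libraries are of batch 2, and the 2 of a day deviate from their mean by equal and opposite amounts. Pairs with an sh004 library therefore say nothing about batch, and the medians and lowest value over all pairs come from such pairs. Among control and sh003 libraries of the same batch r was 0.716 to 0.942. A fit with batch as a block (7 residual degrees of freedom, prior 3.03) was therefore run for every monolayer comparison and is printed beside the main values. The block was planned as an alternative before the data were examined, and its use beside the main values was decided after. The first principal component (68.7% of the variance) parts the batch 1 libraries from the others.

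Fixed gene lists, 21 tested per comparison, were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, which asks only whether a list's genes move one way. Adjustment was over the lists of a comparison, 294 tests in all, of which 86 were called at the preset and 6 at the estimated correlation. Members are counted over all genes and adjusted over the list alone. Read-outs of called genes in other tables were ranked among 10000 random lists matched in 20 expression bins. Overlaps between comparisons that share controls were set beside 20 simulations of unchanged groups.

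Groups, comparisons, tests, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule takes up to 8 called genes per direction with the largest change, a mean RPKM of at least 2 and groups that do not overlap, or the 4 smallest p as values where fewer passed, up to 4 called members per list or the 2 largest as values, and the 10 highest and lowest ratios in KELLY above 0.2 RPKM. NFKBIA and OR2I1P were drawn or named after their values were seen.

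The fits were tested on simulated data with 100 changed genes. At a true log2 change of 1 the main fit recovered 27% to 46% of them in the monolayer knockdown comparisons, the blocked fit 53% to 73% and the sphere fit 21%. At a log2 change of 2 recovery was 77% to 84%, 89% to 95% and 93%, with 1 to 13 false calls per comparison.

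Alternatives were other pseudocounts (0.1, 1), no filter, a filter at RPKM 3, median-ratio and quantile scaling, robust empirical Bayes, a fold of at least 2, only the groups compared, subsets of libraries and batches, each library left out, voom on the recovered reads, and combinations with the batch block. Others leave out pseudogenes and genes without reads in batch 1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.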

Results

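RNA was sequenced from human neuroblastoma cells to ask what depends on CASC15, a long non-coding RNA gene of the 6p22.3 neuroblastoma risk locus, and on SOX9, a transcription factor gene. SH-SY5Y cells carried a scrambled control shRNA, an shRNA against the CASC15-003 transcript (sh003) or an shRNA against the CASC15-004 transcript (sh004), with a pair of shRNAs, sh1 and sh2, per transcript. They were collected at day 0 in serum, after 7 days of retinoic acid, which drives these cells towards neurons, or as spheres. The 15 monolayer libraries were 3 control, 3 sh003 and 2 sh004 at day 0, and 2 control, 3 sh003 and 2 sh004 at day 7. The 5 sphere libraries were 1 control, 2 sh003 and 2 sh004. KELLY cells, another neuroblastoma line, gave 1 library with a control siRNA and 1 with a SOX9 siRNA. Assigned reads per library ranged from 11.9 to 62.1 M. Values are RPKM, reads per kilobase and M assigned reads, given as mean ± SD, and p-values come from limma over 19461 monolayer or 14711 sphere genes.

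Retinoic acid also shows which libraries were treated. CYP26A1, whose enzyme degrades retinoic acid, lay at 0.271 RPKM or lower in all 8 day 0 libraries and at 9.001 to 687 in all 7 day 7 libraries, which includes the pair of sh003 libraries whose differentiation tags contradict their titles. Libraries were grouped by title.

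CASC15, the target, was read as the sum of its isoforms, so the loss of a single transcript is not resolved. Control libraries gave 1.52, 1.31 and 2.38 RPKM at day 0 and 3.33 and 3.26 at day 7. The sh003 libraries gave 2.65 (sh1), 1.95 and 1.57 (sh2) at day 0 and 2.08 (sh1), 3.27 and 3.38 (sh2) at day 7. The sh004 libraries gave 1.16 (sh1) and 1.14 (sh2) at day 0 and 1.31 (sh1) and 1.48 (sh2) at day 7. Spheres gave 2.15 in the control, 1.63 and 2.46 with sh003 sh1 and sh2, and 1.59 and 1.60 with sh004 sh1 and sh2. No knockdown comparison passed for CASC15. With sh003 it was not lower at day 0 (log2 change 0.20, SE 0.24, adjusted p = 1.00), and with sh004 at day 7 both libraries lay under both controls (log2 change -1.01, SE 0.29, adjusted p = 0.520; adjusted p = 0.133 with the batch block). With the batch block CASC15 rose from day 0 to day 7 in controls (log2 change 0.97, SE 0.19, adjusted p = 0.0182) and with sh003 (log2 change 0.62, SE 0.17, adjusted p = 0.0388), calls that the fit without block did not make (adjusted p = 0.205 and 0.404). The KELLY libraries gave 2.56 with the control and 3.09 with the SOX9 siRNA.

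The axis named in the series title runs from the deubiquitinase USP36 through the chromatin remodeller CHD7 to SOX9. SOX9 passed in no comparison. It was higher than control at day 0 with sh003 (log2 change 1.38, SE 0.63, adjusted p = 0.862) and at a similar level with sh004 when batches are pooled (log2 change 0.08, SE 0.70, adjusted p = 1.00; 10.9 ± 1.69 against 12.4 ± 9.13 RPKM). At day 7 it was at 0.80 with sh003 (adjusted p = 0.991) and 1.08 with sh004 (adjusted p = 0.741). Under the batch block it was above control in all 4, at 1.38 and 0.78 at day 0 and 0.98 and 1.60 at day 7 with sh003 and sh004 (adjusted p = 0.320, 1.00, 0.473 and 0.331). It was also higher in spheres with sh003 (log2 change 1.81, SE 0.34, adjusted p = 0.167) and sh004 (log2 change 2.14, SE 0.34, adjusted p = 0.0868). Its control day 0 libraries alone ranged from 4.40 to 22.3 RPKM. CHD7 was -0.52 with sh003 at day 0 (SE 0.23, adjusted p = 0.850) and -0.67 at day 7 (SE 0.26, adjusted p = 0.602), but 0.17 in sh003 spheres (adjusted p = 0.706). With sh003 the blocked values were -0.52 and -0.63 (adjusted p = 0.267 and 0.201). With sh004 it was at -0.27 at day 0, -0.10 at day 7 (0.02 with the batch block) and -0.71 in spheres (adjusted p = 1.00, 0.898, 0.978 and 0.175). USP36 and SOX4, the coding neighbour of CASC15, passed in no comparison, and NBAT1, the antisense partner, stayed under the level that was tested.

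**Figure D1:**
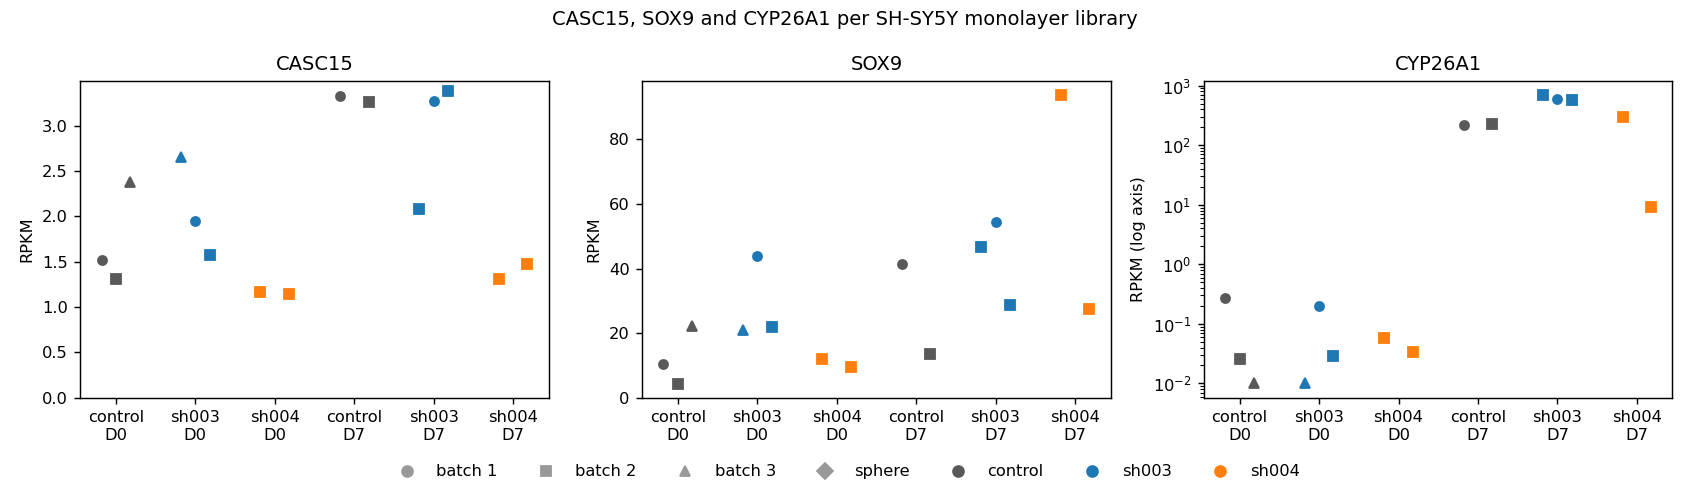
RPKM of CASC15 and SOX9 (linear axes) and CYP26A1 (log axis, values under 0.01 drawn at 0.01) in each SH-SY5Y monolayer library, by group (control grey, sh003 blue, sh004 orange), with circles for batch 1, squares for batch 2 and triangles for batch 3. CYP26A1 separates the 7 day 7 libraries from the 8 at day 0, while CASC15 overlaps between control and sh003.

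Retinoic acid was compared with day 0 in control cells first, to see the response the knockdowns act on. No untreated library was taken at day 7. Effects of retinoic acid and of 7 days in culture therefore cannot be told apart in any comparison of day 7 with day 0. Genes that handle or bind retinoic acid were among the largest rises: CYP26B1, a degrading enzyme (0.346 ± 0.501 to 1033 ± 146 RPKM, log2 change 10.40, SE 0.72, adjusted p = 1.09e-04), CYP26A1 (8.57), DHRS3, a retinal reductase (6.01), CRABP2, a retinoic acid carrier (4.66), and the receptor RARB (4.37). The neurotrophin receptor NTRK2 rose by 5.02 (SE 0.32, adjusted p = 1.06e-04) and RET by 3.34. SAMD11 (-4.36), the neuropeptide receptor ADCYAP1R1 (-3.34), the homeobox genes MSX2 (-3.00) and SIX3 (-2.89), and MYC (-2.34) fell. limma called 137 up and 49 down of 19461 genes in 2 against 3 libraries, and 979 up and 515 down with the batch block. All 186 and 1194 of the 1494 had groups that did not overlap. Among unselected genes chance gives this in 20% for 2 libraries against 3, if libraries are exchangeable. Calls are chosen for a difference between these same groups, so non-overlap follows largely from the call. The count was 62 without control batch 1 day 0, 42 without control batch 1 day 7, 79 without control batch 2 day 0, 36 without control batch 2 day 7, 111 without sh003 sh2 batch 2 day 7 and 107 without sh004 sh1 batch 2 day 0 or sh004 sh2 batch 2 day 0. With the block it was 198 without control batch 1 day 0, 146 without control batch 1 day 7, 592 without control batch 2 day 0, 116 without control batch 2 day 7, 890 without sh003 sh2 batch 1 day 7, 923 without sh003 sh2 batch 2 day 0, 2693 without sh004 sh1 batch 2 day 7 and 2695 without sh004 sh2 batch 2 day 7.

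Among gene lists in controls, the retinoic acid list rose (12 of 14 measured higher, median log2 change 2.47, camera adjusted p = 1.99e-13, adjusted p = 0.0320 with an estimated correlation), with 7 members called over all genes and 11 up adjusted over the list alone. With the block this list did not pass with an estimated correlation. The cell cycle list fell in controls (0 of 25 measured higher, median log2 change -0.998, camera adjusted p = 2.31e-15, adjusted p = 0.157 with an estimated correlation), with sh003 (0 of 25 measured higher, median log2 change -1.34, camera adjusted p = 3.45e-20, adjusted p = 0.106 with an estimated correlation) and with sh004 (0 of 25 measured higher, median log2 change -0.84, camera adjusted p = 2.48e-12, adjusted p = 0.204 with an estimated correlation). The reference genes were also called lower in controls (median -0.49, adjusted p = 0.0171, adjusted p = 0.509 with an estimated correlation). Their medians were -0.32 with sh003 and -0.23 with sh004, not called. For sh003 5 cell cycle members passed over all genes (RRM2 -1.69, TYMS -1.28, MCM4 -1.14, CDK1 -1.64 among them) and 25 adjusted over the list alone. Noradrenergic genes fell in controls (adjusted p = 7.20e-07, adjusted p = 0.218 with an estimated correlation), with SIX3 called there and DDC (-3.86) and the noradrenaline transporter SLC6A2 (-2.91) called with sh003. The sterol regulator INSIG1 rose in controls (1.86) and with sh003 (2.12), and the cholesterol list rose with sh004 (15 of 15 measured higher, median log2 change 0.90, camera adjusted p = 4.78e-11, adjusted p = 0.0224 with an estimated correlation). The cholesterol call did not hold with the block and an estimated correlation.

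**Figure D2:**
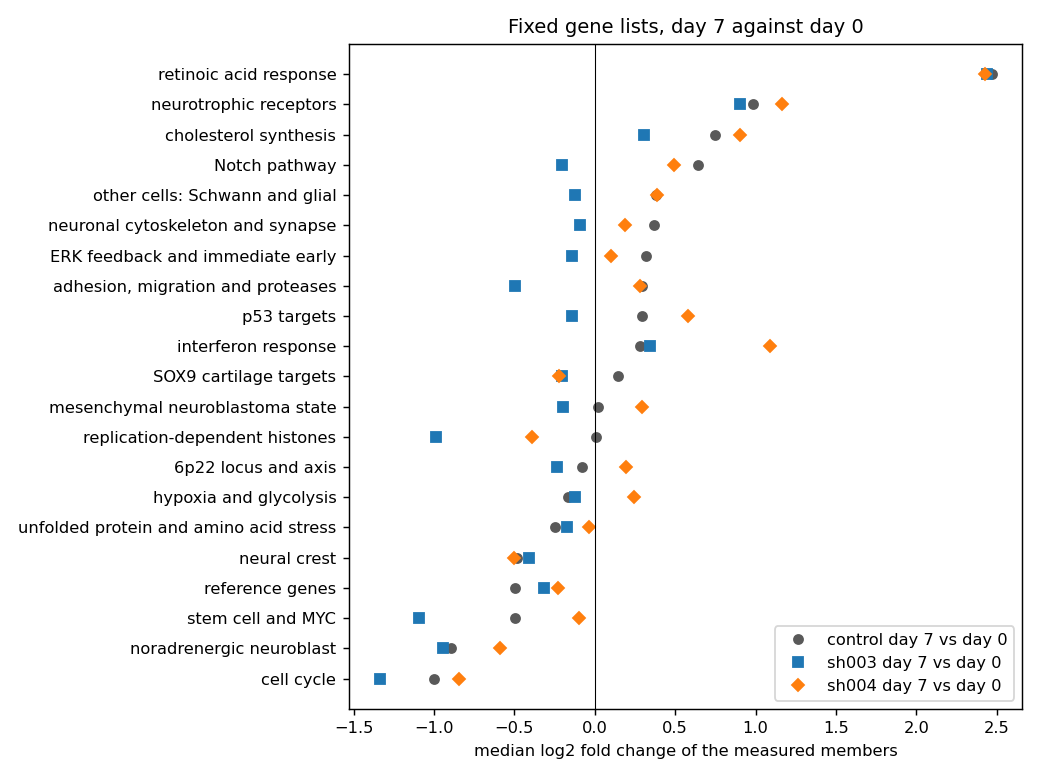
Median log2 change from day 0 to day 7 of the measured members of each fixed gene list (horizontal axis), with grey circles for control, blue squares for sh003 and orange diamonds for sh004. The retinoic acid list lies right of 0 in all 3, with medians of 2.47, 2.44 and 2.42, and the cell cycle list left of 0.

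With sh003, 305 genes were higher and 153 lower at day 7 than at day 0 in 3 against 3 libraries, and 1684 and 1095 with the batch block. CYP26B1 (10.45), CYP26A1 (10.07), the scavenger receptor COLEC12 (5.71) and complement factor CFI (5.13) rose, and NPY, a sympathetic neuropeptide (955 ± 527 to 32.1 ± 28.0 RPKM, log2 change -5.13, SE 0.75, adjusted p = 0.00618), the BMP antagonist GREM1 (-4.55), ID4 (-4.42) and IGFBP3 (-4.02) fell. All 458 and 2000 of the 2779 had non-overlapping groups, which follows largely from being called. Among unselected genes chance gives this in 10%. The count was 186 without sh003 sh2 batch 1 day 0, 190 without sh003 sh2 batch 1 day 7, 151 without sh003 sh2 batch 2 day 0, 124 without sh003 sh2 batch 2 day 7, 290 without sh004 sh1 batch 2 day 0 or sh004 sh2 batch 2 day 0, 780 without sh004 sh1 batch 2 day 7 and 781 without sh004 sh2 batch 2 day 7. With the block it was 945 without sh003 sh2 batch 1 day 0, 901 without sh003 sh2 batch 1 day 7, 343 without sh003 sh2 batch 2 day 0 and 1113 without sh003 sh2 batch 2 day 7. With sh004, 2 against 2 libraries gave 49 up and 25 down, and 277 up and 133 down with the block. CYP26B1 (8.77), CYP26A1 (6.62) and CRABP2 (5.46) rose, though the sh004 libraries differed widely at day 7 for CYP26B1 (782 and 85.7 RPKM) and CYP26A1 (301 and 9.001). Without sh1 or sh2 at day 7 the CYP26B1 change was 7.17 or 10.36 and the CYP26A1 change 4.12 or 9.11. SAMD11 (-4.45), DUSP2 (-3.52) and the Wnt antagonist DKK1 (-2.94) fell. The retinoic acid list passed with both (adjusted p = 0.0285 with sh003 and 0.00630 with sh004, with an estimated correlation). With the block and an estimated correlation it held with sh004 only. The sh004 count was 45 without sh003 sh1 batch 2 day 7, 16 without sh004 sh1 batch 2 day 0, 42 without sh004 sh1 batch 2 day 7 and 15 without sh004 sh2 batch 2 day 0. With the block it was 269 without control batch 1 day 0, 268 without control batch 1 day 7, 260 without control batch 2 day 7, 265 without sh003 sh2 batch 1 day 0, 192 without sh004 sh1 batch 2 day 0, 81 without sh004 sh2 batch 2 day 0 and 1474 without sh004 sh2 batch 2 day 7.

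In all 3 backgrounds 33 genes rose and 19 fell, 152 and 94 with the batch block. Controls and sh003 shared 117 calls of one sign, where independent lists give 2.53 and simulated unchanged groups 0. Unchanged groups give few or no calls, so a simulated 0, here and for sh004, is no check on the shared count. Across genes, which are not independent replicates, the changes correlated at r = 0.679 (covariance 0.238, simulated 0.00302). Controls and sh004 shared 60 (independent 0.408, simulated 0; r = 0.546, covariance 0.177, simulated -1.44e-05). These comparisons share no library, but they share batches, which the simulations without block leave out. With the block they shared 1046 (independent 114) and 265 (independent 17.5). Median-ratio scaling moved the up and down split in controls to 101 up and 60 down and with sh003 to 255 up and 210 down, and with the block to 715 up and 822 down and 1358 up and 1514 down. RET and NTRK2 rose in all 3 backgrounds, RET by 3.46 with sh003 and 3.00 with sh004.

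sh003 was compared with control at day 0 to ask what changes with the CASC15-003 shRNAs in growing cells. IL33, an alarmin cytokine, rose (5.67 ± 0.0837 RPKM against 0.238 ± 0.232, log2 change 3.11, SE 0.29, adjusted p = 0.00704) in all 3 libraries against 3. It was the 1 call, with 1125 genes at an unadjusted p under 0.05 and 1 by voom. With the batch block limma called 39 up and 10 down, and 39 by voom. Of the 49, 45 had non-overlapping groups, which follows largely from being called. Among unselected genes chance gives this in 10%. Of the 49 calls, complement component C7 (200.3 ± 92.3 RPKM against 15.1 ± 7.75, log2 change 3.70, SE 0.53, adjusted p = 0.0309), the prostaglandin enzyme PTGS1 (3.25), the matrix proteoglycan DCN (3.09), the differentiation inhibitor ID4 (3.01) and the immediate early factor EGR1 (2.46) rose. The serotonin receptor HTR3A (-2.12), the synaptic protein RIMBP2 (-1.47) and the cadherin CELSR2 (-0.94) fell. Without block DCN, HTR3A and RIMBP2 did not pass (adjusted p = 0.0750, 0.329 and 0.106). The count was 0 without control batch 2 day 0 or sh003 sh2 batch 1 day 0 or sh003 sh2 batch 2 day 0, 23 without control batch 3 day 0, 9 without sh003 sh1 batch 3 day 0, 2 without sh003 sh2 batch 2 day 7 and 5 without sh004 sh1 batch 2 day 7 or sh004 sh2 batch 2 day 7. With the block it was 1 to 262 without single libraries, staying within 1.5 times only when the one left out was sh003 sh1 batch 2 day 7.

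For none of the 86 list calls made in this study did the median log2 change take the other sign under median-ratio or quantile scaling. The list tests themselves were not rerun under these scalings. At day 0 with sh003, mesenchymal genes stood higher and neuroblast genes lower under camera with a preset correlation. The mesenchymal list rose (20 of 20 measured higher, median log2 change 0.76, camera adjusted p = 1.16e-11, adjusted p = 0.164 with an estimated correlation; 0 up and 0 down over all genes, 1 up and 0 down adjusted over the list alone; COL5A1 3.49 and FOSL2 1.53 as values). The adhesion and protease list rose (18 of 23 measured higher, median log2 change 0.83, camera adjusted p = 6.83e-11, adjusted p = 0.117 with an estimated correlation), with 0 up and 0 down over all genes, 5 up and 0 down adjusted over the list alone and TNC at 2.09 as a value. ERK feedback genes rose with either correlation (13 of 16 measured higher, median log2 change 0.43, camera adjusted p = 2.65e-07, adjusted p = 0.0284 with an estimated correlation). The cell cycle list fell (0 of 25 measured higher, median log2 change -0.53, camera adjusted p = 2.02e-06, adjusted p = 0.347 with an estimated correlation; 0 up and 0 down over all genes, 0 up and 0 down adjusted over the list alone). Noradrenergic genes fell too (adjusted p = 8.83e-05, adjusted p = 0.347 with an estimated correlation; CHGA -1.72, HAND1 -1.39). With the batch block the adhesion and interferon lists also held with an estimated correlation (adjusted p = 0.0433 and 0.0433).

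For sh004 at day 0, 2 libraries against 3, limma called 0 genes, with 378 at an unadjusted p under 0.05, and voom called 0, with 393 at an unadjusted p under 0.05. Blocked by batch, limma called 0, with 719 at an unadjusted p under 0.05. It called 2 without sh004 sh2 batch 2 day 0. The smallest p values belonged to TULP3, a cilium trafficking gene (21.9 ± 2.79 RPKM against 8.53 ± 0.743, log2 change 1.31, SE 0.20, adjusted p = 0.722), COX7C (1.10), PLPPR3 (-2.20) and the neuronal filament gene PRPH (-1.20), given as values. The reference genes were called higher (median 0.25, adjusted p = 0.0114, adjusted p = 0.992 with an estimated correlation), with a median of -0.01 under the block. The cell cycle list was called higher (20 of 25 measured higher, median log2 change 0.16, camera adjusted p = 0.0114, adjusted p = 0.992 with an estimated correlation), but with the block its median was -0.18 (adjusted p = 0.278). The p53 list was called lower and the amino acid stress list higher, with adjusted p = 0.0114 and 0.0114, and adjusted p = 0.992 for both with an estimated correlation.

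At day 7 the question is whether sh003 alters cells under differentiation. In 3 libraries against 2, limma called 0 genes, with 1405 at an unadjusted p under 0.05, and voom called 0, with 1533 at an unadjusted p under 0.05. With the batch block HEY1, a Notch target repressor, fell (6.22 ± 0.554 RPKM against 23.4 ± 5.65, log2 change -1.82, SE 0.18, adjusted p = 0.0230), the 1 call, and lay lower in 3 of 3 libraries (adjusted p = 0.460 without block). ENPP2 (-2.33), ENC1 (-2.43), ST8SIA6 (2.22) and the protease MMP2 (1.33) are values. The neuronal list fell (1 of 22 measured higher, median log2 change -1.19, camera adjusted p = 3.05e-08, adjusted p = 0.428 with an estimated correlation; 0 up and 0 down over all genes, 0 up and 0 down adjusted over the list alone; ELAVL3 -2.58, INA -2.19). So did the cell cycle list (0 of 25 measured higher, median log2 change -0.77, camera adjusted p = 1.61e-10, adjusted p = 0.428 with an estimated correlation; 0 up and 0 down over all genes, 0 up and 0 down adjusted over the list alone) and the noradrenergic list (6 of 21 measured higher, median log2 change -1.03, camera adjusted p = 2.70e-04, adjusted p = 0.435 with an estimated correlation; 0 up and 0 down over all genes, 0 up and 7 down adjusted over the list alone; CHGA -3.51, DDC -2.89). The mesenchymal list rose (17 of 20 measured higher, median log2 change 0.65, camera adjusted p = 1.46e-06, adjusted p = 0.428 with an estimated correlation; COL5A1 2.32, SPARC 1.62). The unblocked count was 8 without sh004 sh1 batch 2 day 7 or sh004 sh2 batch 2 day 7. The blocked count was 0 to 588 without single libraries, staying within 1.5 times only when the one left out was sh004 sh1 batch 2 day 0 or sh004 sh2 batch 2 day 0.

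For sh004 at day 7, 2 libraries against 2, limma called 0 genes, with 1564 at an unadjusted p under 0.05, and voom called 0, with 1594 at an unadjusted p under 0.05. Both sh004 libraries are of batch 2, and the controls are 1 library of batch 1 and 1 of batch 2. With the batch block limma called 34 up and 10 down, and 6 genes by voom. There the batch 1 control enters only through a batch offset estimated from control and sh003 libraries. All 44 calls had non-overlapping groups, which follows largely from being called. Among unselected genes chance gives this in 33.3% for 2 against 2. Among the genes that rose were the adhesion receptor VCAM1 (9.32 ± 1.84 RPKM against 0.0408 ± 0.0577, log2 change 4.16, SE 0.20, adjusted p = 1.42e-05), complement C3 (5.45), the iron-binding lipocalin LCN2 (5.08), TNFAIP6 (4.13), the survival factor BCL2A1 (3.82) and the NF-κB inhibitor TNFAIP3 (3.53). Several lay near 0 in controls, so their log2 size depends on the 0.5 added. HEY1 fell (5.99 ± 0.0155 RPKM against 23.4 ± 5.65, log2 change -1.89, SE 0.20, adjusted p = 0.0110), as did the collagen gene COL26A1 (-2.26). The same genes were also high without an sh004 shRNA: of the 34 that rose, 33 were higher and 26 at least 2-fold higher in the batch 3 control at day 0 than in the other day 0 controls. The sh003 library of batch 3 was high too (median log2 ratio 2.33 to the batch 2 control). These 2 libraries make up batch 3, so the block takes up what they share. The SEs and p-values of the blocked calls leave out that difference between cultures and may be too small. The unblocked count was 1 without sh003 sh1 batch 3 day 0 and 4 without sh004 sh1 batch 2 day 7. The blocked count was 2 to 192 without single libraries, staying within 1.5 times only when the one left out was control batch 3 day 0 or sh003 sh1 batch 3 day 0 or sh004 sh1 batch 2 day 0 or sh004 sh2 batch 2 day 0.

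The sh004 day 7 libraries differ from each other: on the second principal component sh2 lay at 8.03, where the other day 7 libraries lay at -60.2 to -26.5 and the day 0 libraries at -4.24 to 52.5. Lists with sh004 at day 7, which average both, rose for interferon (7 of 8 measured higher, median log2 change 0.93, camera adjusted p = 6.92e-05, adjusted p = 0.302 with an estimated correlation; 0 up and 0 down over all genes, 2 up and 0 down adjusted over the list alone; IFI44 1.15, IFI6 1.08), hypoxia (11 of 13 measured higher, median log2 change 0.52, camera adjusted p = 5.91e-05, adjusted p = 0.175 with an estimated correlation; VEGFA 1.16, LDHA 0.98) and cholesterol synthesis (14 of 15 measured higher, median log2 change 0.30, camera adjusted p = 7.15e-04, adjusted p = 0.302 with an estimated correlation; FDPS 0.64). So did amino acid stress (13 of 15 measured higher, median log2 change 0.32, camera adjusted p = 5.91e-05, adjusted p = 0.175 with an estimated correlation) and the cell cycle list (19 of 25 measured higher, median log2 change 0.33, camera adjusted p = 4.31e-04, adjusted p = 0.764 with an estimated correlation), the latter not called with the block (median 0.10, adjusted p = 0.0538). Neuronal genes were called lower (adjusted p = 0.0238, adjusted p = 0.775 with an estimated correlation) but not with the block (adjusted p = 0.0538). The reference genes rose too (median 0.34, adjusted p = 7.15e-04, adjusted p = 0.508 with an estimated correlation), while the median of all genes was -0.148.

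**Figure D3:**
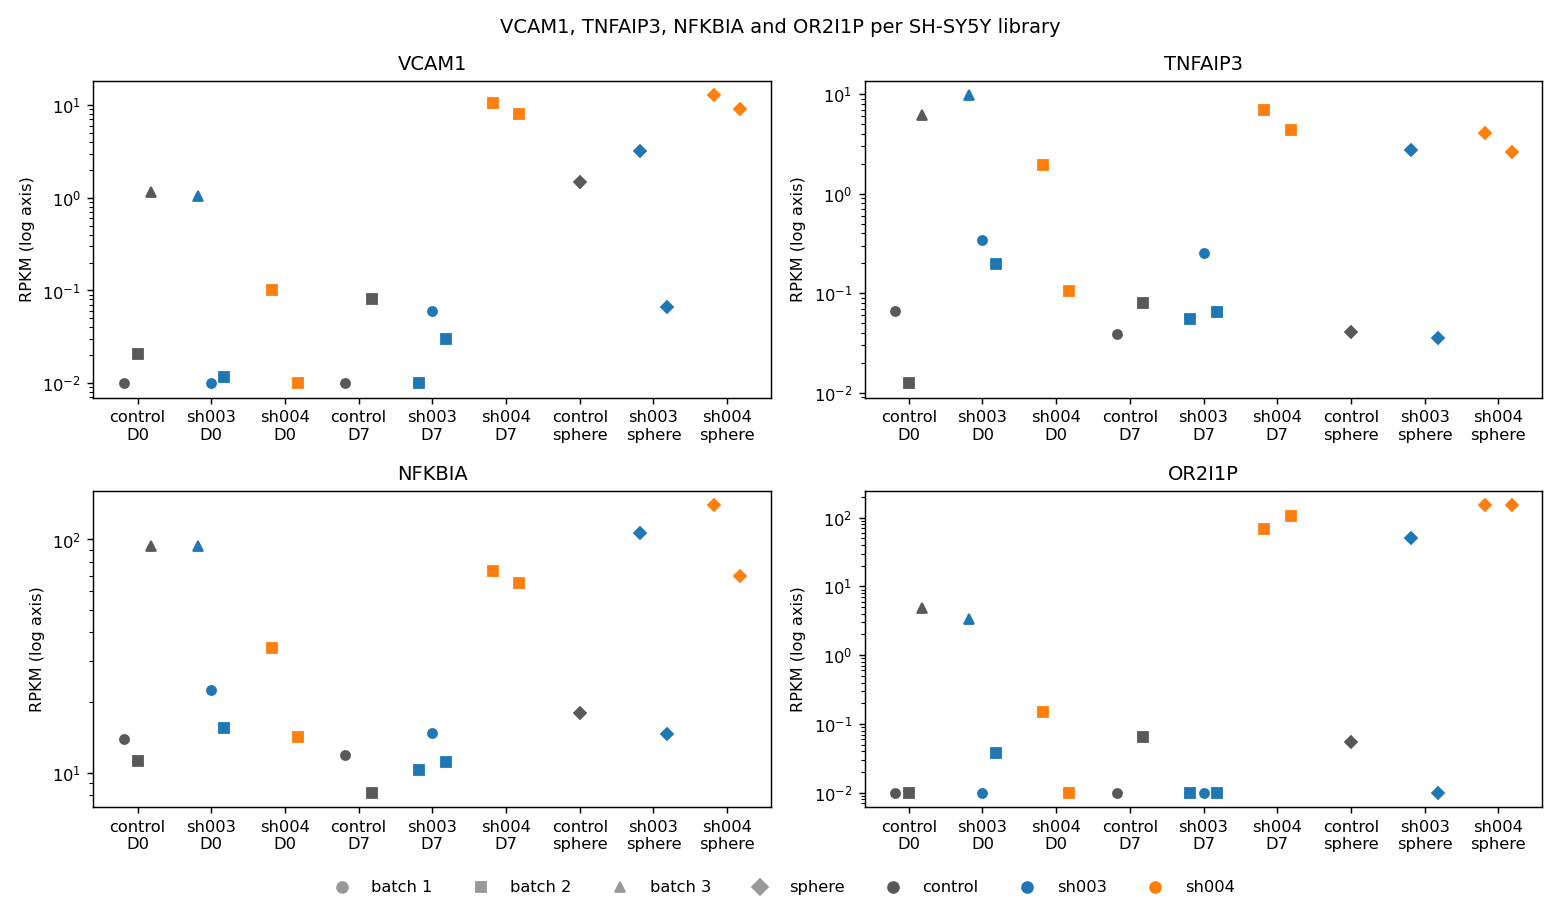
RPKM of VCAM1, TNFAIP3, NFKBIA and OR2I1P in each SH-SY5Y library on log axes, by group (control grey, sh003 blue, sh004 orange), with circles for batch 1, squares for batch 2, triangles for batch 3 and diamonds for spheres; values under 0.01 are drawn at 0.01. The sh004 day 7 and sphere libraries are high, and so are the batch 3 day 0 libraries of control and sh003.

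Whether the knockdowns alter the change from day 0 to day 7 was tested as an interaction. For sh003 limma called 0 genes, with 284 at an unadjusted p under 0.05, and voom called 0, with 240 at an unadjusted p under 0.05, and 0 genes with the batch block (731 at an unadjusted p under 0.05), where it called 1 without control batch 3 day 0 or sh003 sh1 batch 3 day 0 or sh003 sh1 batch 2 day 7 or sh003 sh2 batch 1 day 7. ATP2B1, a calcium pump, and SEMA6A, an axon guidance gene, had the smallest p each way (-1.34 and 1.02, as values). The neuronal list responded less than in controls (3 of 22 measured higher, median log2 change -0.72, camera adjusted p = 6.25e-05, adjusted p = 0.537 with an estimated correlation; GAP43 -2.12, DCX -1.68). For sh004 limma called 0 genes, with 284 at an unadjusted p under 0.05, and voom called 0, with 265 at an unadjusted p under 0.05. With the block VCAM1 rose more than in controls (4.08, SE 0.26, adjusted p = 2.37e-04). So did OR2I1P, an olfactory receptor pseudogene chosen after its values were seen (7.23, SE 0.33, adjusted p = 1.55e-05). It was listed at 0 in all 4 batch 1 libraries, as were many genes of its chromosome region. Those zeros enter the fit as control and sh003 values, so its SE and p-value may be too small. The same holds for VCAM1, since the block takes up its high values in the batch 3 day 0 libraries. Block and voom together called 0. The interferon list rose more (8 of 8 measured higher, median log2 change 0.80, camera adjusted p = 3.08e-06, adjusted p = 0.268 with an estimated correlation). The sh004 count was 1 without sh003 sh1 batch 3 day 0 or sh004 sh1 batch 2 day 7. With the block it was 4 without control batch 1 day 0 or control batch 3 day 0 or sh003 sh1 batch 3 day 0, 5 without sh004 sh1 batch 2 day 0 or sh004 sh2 batch 2 day 0, 7 without sh004 sh1 batch 2 day 7 and 6 without sh004 sh2 batch 2 day 7.

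The shRNA targets were also compared with each other. At day 0 IL33 was higher with sh003 than sh004 (5.67 ± 0.0837 RPKM against 0.246 ± 0.0501, log2 change 3.05, SE 0.33, adjusted p = 0.0263), the 1 call with or without block, of 1409 genes at an unadjusted p under 0.05. The adhesion list was higher with sh003 (21 of 23 measured higher, median log2 change 0.92, camera adjusted p = 1.82e-07, adjusted p = 0.296 with an estimated correlation; 0 up and 0 down over all genes, 7 up and 0 down adjusted over the list alone; PLAU 1.82, TNC 1.72). At day 7 ST8SIA6, a sialyltransferase (10.8 ± 3.16 RPKM against 0.860 ± 0.741, log2 change 3.13, SE 0.41, adjusted p = 0.0435), COL26A1 (2.60) and the zinc finger gene PLAGL1 (1.64) were higher and BCL2A1 lower (-3.92), 3 up and 1 down without block and 70 up and 69 down with it. The cell cycle list was lower with sh003 (0 of 25 measured higher, median log2 change -1.20, camera adjusted p = 5.94e-18, adjusted p = 0.282 with an estimated correlation; 0 up and 0 down over all genes, 0 up and 20 down adjusted over the list alone; CDC20 -2.002, CCNB2 -1.94). The reference genes were also called lower with sh003 at day 7 (median -0.57, adjusted p = 0.00554, adjusted p = 0.527 with an estimated correlation) and at day 0 (median -0.37, adjusted p = 0.0318, adjusted p = 0.499 with an estimated correlation). The day 0 count was 0 to 1 without single libraries, staying within 1.5 times only when the one left out was control batch 1 day 0 or control batch 3 day 0 or sh003 sh2 batch 1 day 7. Blocked by batch it was 0 to 3 without single libraries, staying within 1.5 times only when the one left out was control batch 1 day 0 or sh003 sh2 batch 1 day 7. The day 7 count was 0 to 339 without single libraries, staying within 1.5 times only when the one left out was control batch 3 day 0 or sh003 sh2 batch 1 day 7. With the block it was 7 to 2268 without single libraries, staying within 1.5 times only when the one left out was control batch 3 day 0 or sh003 sh1 batch 3 day 0 or sh004 sh1 batch 2 day 0 or sh004 sh2 batch 2 day 0.

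To ask whether the knockdowns share an effect, their calls were overlapped against the same controls. No overlap could arise at day 0, where sh004 had 0 calls, or in spheres, where sh003 had 0. At day 7 HEY1 fell with both under the batch block, 1 gene where independent lists give 5.14e-04 and simulated unchanged groups 0 (without block neither had a call). Unchanged groups give few or no calls, so the simulated 0 is no check on this overlap. Shared controls alone tie the changes together: at day 0 r across genes was 0.155 (simulated 0.449, covariance 0.0351, simulated 0.224) and 0.475 with the block (simulated 0.400, covariance 0.0643, simulated 0.0334). At day 7 r was 0.559 (simulated 0.550, covariance 0.238, simulated 0.332) and 0.408 with the block (simulated 0.553, covariance 0.0929, simulated 0.0543). In spheres it was 0.170 (simulated 0.666, covariance 0.0951, simulated 0.0952). Without block the simulation puts the spread between batches into independent libraries, though control and sh003 libraries of the same batch correlated at 0.716 to 0.942. The unblocked simulated values in monolayers are therefore no fair reference. The sh004 groups also hold another mix of batches than controls, as does sh003 at day 7, which can tie changes together. The controls are too few to split, so part of any excess may come from shared controls.

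Spheres select for cells that grow without attachment. With 1 control sphere the spread of controls is not measured, so calls against it are differences from that library and cannot be assigned to the shRNAs. With sh004, 2 libraries against 1, limma called 18 up and 1 down of 14711 genes, and voom 3. The chemokine CCL19 reached 73.0 ± 6.99 RPKM and TNFAIP6 24.4 ± 10.7, both listed at 0 in the control. The lipolysis inhibitor G0S2 (5.79, SE 0.53, adjusted p = 0.0391), IGFBP3 (5.54), complement C1S (5.05) and HLA-C (4.57) were higher, and the growth inhibitor CDKN1C was lower (-3.11, adjusted p = 0.0391). The cell cycle list was lower (0 of 25 measured higher, median log2 change -0.67, camera adjusted p = 5.65e-05, adjusted p = 0.702 with an estimated correlation; 0 up and 0 down over all genes, 0 up and 8 down adjusted over the list alone; BUB1B -1.57). So was the neuronal list (3 of 21 measured higher, median log2 change -1.17, camera adjusted p = 3.06e-04, adjusted p = 0.518 with an estimated correlation; 0 up and 0 down over all genes, 0 up and 11 down adjusted over the list alone; INA -2.85). The interferon list was higher (7 of 7 measured higher, median log2 change 1.23, camera adjusted p = 3.56e-04, adjusted p = 0.518 with an estimated correlation; 0 up and 0 down over all genes, 4 up and 0 down adjusted over the list alone; IFIH1 2.83). The cholesterol list was lower in these spheres (2 of 15 measured higher, median log2 change -0.73, camera adjusted p = 0.00816, adjusted p = 0.753 with an estimated correlation), against its rise with sh004 at day 7. The count was 235 without the sh003 sh1 sphere, 356 without the sh003 sh2 sphere and 0 without the sh004 sh1 sphere or the sh004 sh2 sphere.

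With sh003, 2 spheres against 1, limma called 0 genes, with 2811 at an unadjusted p under 0.05, and voom called 0, with 2975 at an unadjusted p under 0.05. TFPI2, a protease inhibitor, had the smallest p (4.54, SE 0.38, adjusted p = 0.0811), and HLX (-3.59) and the neuronal genes NSG2 (-3.71) and STMN4 (-3.94) were lower as values. The hypoxia list was higher (12 of 13 measured higher, median log2 change 1.08, camera adjusted p = 1.38e-05, adjusted p = 0.695 with an estimated correlation; 0 up and 0 down over all genes, 6 up and 0 down adjusted over the list alone; VEGFA 2.92, ADM 2.38). The neuronal list was lower (2 of 21 measured higher, median log2 change -0.70, camera adjusted p = 0.00266, adjusted p = 0.695 with an estimated correlation). The count was 120 without the sh003 sh2 sphere. Between knockdowns 3395 up and 2470 down genes were called, 6080 by voom, in 2 against 2 libraries. The signalling regulator RGS4 (4.52) and CDKN1C (4.50) were higher with sh003 and CCL19 (-6.49), the chemokine CXCL10 (-5.78) and CHI3L1 (-5.31) lower. CHD7 was higher with sh003 than sh004 (log2 change 0.88, SE 0.20, adjusted p = 0.0185), as were MYC (3.05) and VEGFA (3.46). This count was 2365 without the sh003 sh2 sphere, 2702 without the sh004 sh1 sphere and 26 without the sh004 sh2 sphere. The up and down split was 2676 up and 3007 down under median-ratio scaling.

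Genes called under the batch block were then read in tables with other controls. The sphere ratios rest on 1 control sphere, and the ranks treat genes as independent. Genes that move together can therefore rank at an extreme without an effect of the shRNA. The 39 genes higher with sh003 at day 0 had a median log2 ratio of 0.61 in sh003 spheres (26 measured, above 9999 of 10000 expression-matched random lists) and -0.08 in sh004 spheres (above 7376). Those lower gave 0.51 in sh003 spheres (6 measured), the other direction. The 34 genes higher with sh004 at day 7, LCN2 and C3 among them, gave 2.80 in sh004 spheres (33 measured, above all 10000) and 0.97 in sh003 spheres (above all 10000). The 10 lower gave -1.39 in sh004 spheres (6 measured, above 1) and 0.11 in sh003 spheres (above 6500). HEY1 was at -1.58 in sh003 and -2.53 in sh004 spheres. In KELLY cells with the SOX9 siRNA the sh003 genes gave 0.06 (above 5162 of 10000) and the sh004 genes -0.32 (13 measured, above 7).

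KELLY cells with the SOX9 siRNA ask what SOX9 sustains in a MYCN-amplified line. With 1 library each there is no replicate check and no p-value, and 95% exact intervals cover counting error only. SOX9 itself went from 5.61 to 0.974 RPKM, log2 ratio -2.05 with 0.5 added to each value, on 562 and 92 reads (interval of the log2 read rate ratio -2.86 to -2.20). Some immediate early genes were far higher with the siRNA, FOS (0.291 to 98.5 RPKM, log2 ratio 6.97), EGR1 (1.44 to 90.7 RPKM, log2 ratio 5.56), ARC (3.14) and NR4A1 (2.93). Lower were the matrix gene DPT (17.5 to 0.653 RPKM, log2 ratio -3.96), the chemokine CCL2 (-3.37), the endothelin receptor EDNRA (-2.30), S100A4 (-2.18) and the matrix glycoprotein SPARC (-1.86). TH, which starts catecholamine synthesis, was higher (1.52), as was HES1 (1.34), while MYCN was at 787 to 1052 RPKM, log2 ratio 0.42. Of 14340 genes at RPKM 1 or above, 359 were at least 2-fold higher and 214 lower.

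In the lists of the KELLY pair, amino acid stress (median 0.39, 13 of 15 higher, above 9999 of 10000 matched random lists; CHAC1 and ASNS) and hypoxia genes (median 0.36, 9 of 11 higher, above 9981 of 10000 matched random lists; EGLN3 and VEGFA) were higher. Mesenchymal (median -0.28, 4 of 12 higher, above 11 of 10000 matched random lists; SPARC and COL5A1) and neuronal genes (median -0.17, 8 of 22 higher, above 10 of 10000 matched random lists; DPYSL3 and SYN1) were lower. The ERK feedback and immediate early list as a whole lay slightly higher (median 0.18, 12 of 17 higher, above 9669 of 10000 matched random lists). So did cell cycle genes (median 0.14, 17 of 25 higher, above 9932 of 10000 matched random lists). COL9A2, a cartilage gene that SOX9 drives, was at -0.35 on 281 and 197 reads. The retinoic acid and noradrenergic medians lay near 0 (0.01 and 0.03) and change sign under median-ratio scaling.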

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

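The tests chosen only after the result was seen are the reading of the sh004 genes in spheres and in the batch 3 control, the pseudogene share in batch 1, the tests of CYP26A1 in the sh004 sh2 library except the spread of shares, and the splits of the sh003 day 0 comparison.

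A pair of genes changed differently from day 0 to day 7 with sh004 than in controls under the batch block. VCAM1, an adhesion receptor induced by inflammatory signals, rose by a log2 value of 4.08 more (SE 0.263, adjusted p = 2.37e-04), and OR2I1P by 7.23 more (SE 0.328, adjusted p = 1.55e-05), in both sh004 libraries. VCAM1 stood at 10.6 and 8.02 RPKM with sh004 at day 7 and at 0.0816 in the batch 2 control. OR2I1P stood at 69.2 and 106 against 0.0651. OR2I1P was listed at 0 in all 4 batch 1 libraries, as were many genes of the same chromosome region, so its SE and p-value may be too small. Leaving such genes and pseudogenes out kept VCAM1 at 4.08 with adjusted p = 0.00413 under the block.

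Under the batch block the genes higher with sh004 than control at day 7 include TNFAIP3, C3 and BCL2A1. In sh003 sh2 day 7 libraries these genes had a median log2 ratio of batch 2 to batch 1 of -0.0054. This cannot decide on an effect of batch 2. Those libraries enter the blocked fit that chose the genes, and the fit removes differences between batches. Cells of another kind remain open, since epithelial markers written down beforehand were 1.36 RPKM above the same-batch control on average in sh1, driven by KRT18 at 11.02, but -0.245 in sh2, while blood markers differed by -0.0419 and -0.0119. The 34 genes were above all 10000 random lists in sh004 spheres (median log2 ratio 2.80) but also in sh003 spheres (0.97), against the same control sphere, and their median log2 ratio was 1.77 in the batch 3 control at day 0 against the other day 0 controls. These values are consistent with a culture state that SH-SY5Y cells may reach without an sh004 shRNA, and whether the shRNA or the culture brought it about in the sh004 libraries stays open with 2 libraries of 1 batch.

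Batch 1 libraries listed more genes at RPKM 1 or above than their batch 2 counterparts, 16151 against 13792 in day 0 controls. Lower depth is argued against, as drawing batch 2 down to batch 1 depth closed a median of 2.25% of the gap, and so is counting of both strands, with opposite-strand genes only 0.215 above lone genes on the log2 scale (0.0971 to 0.284 over 4 pairs). Genomic DNA stays open, with lone olfactory receptor genes at 1.95 times the batch 2 rate on 8 to 31 reads per library. Of the 3286 genes over the limit in batch 1 only, 68.4% were processed pseudogenes, and 69 coding genes at RPKM 5 or above in all 11 other libraries had 0 reads in batch 1, 54 of them between GABBR1 and DAXX on chromosome 6. A candidate explanation for the pseudogenes is that reads matching several places were counted differently in batch 1, which no processing note states. The zeros need not share that cause. The control and SOX9 siRNA KELLY libraries held 2.24% and 2.25% of reads in processed pseudogenes, yet listed 61 and 62 of the 69 coding genes. The cause of the zeros was not tested.

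CYP26A1 reached 9.001 RPKM in the sh004 sh2 day 7 library and 301 in sh1, and CYP26B1 also differed (85.7 and 782). An exchange with the day 0 library is argued against, since that library showed 0.0333. Over genes called in controls the slope of the change on the control change was 0.777 in sh2 and 0.878 in sh1, and 64.2% of the genes that rose in controls lay within 2 times of the median share of the sh1 level, which leaves a smaller response and a mixture with untreated cells open as a part of the difference. Neither accounts for CYP26A1 by itself: the slopes explain 17.2% of its gap, and the median share of the genes is 25.3 times that of CYP26A1. No biological explanation was tested, and the cause of the low value stays open.

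For comparisons of 3 against 3 libraries, the 10 possible splits are too few for a share under 0.05. The sh003 day 0 comparison gave 1 call in the real split and at most 0 in another, and 49 and at most 6 with the batch block. The sh003 day 7 comparison with day 0 gave 458 and at most 0, and 2779 and at most 1 with the block. In each case 1 of the 10 splits, the real one, gave as many. The other splits are weak comparators. In several at day 0 a batch lies wholly on a single side. Those of day 7 against day 0 mix treated and untreated libraries, which widens the spread. Few calls were therefore likely in them in advance.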

How the results depend on the processing

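Alternatives chosen after the data were seen are voom, leaving out batch 1, every combination with the batch block, leaving out pseudogenes and genes without reads in batch 1, the deposited sphere RPKM, and the naming rule and gene list tests applied to the blocked fit. The batch block itself was planned. The tallies cover only called genes picked by the naming rule, mostly for a large change, so they may overstate how stable all calls are. Over the 180 such results without block, 2921 of 3871 alternative values kept direction and side of the threshold. Of the rest, 949 kept the direction and lost the call, and 1 reversed. For the 203 named results called with the block, 3360 of 4249 were the same and 889 weaker. In each paragraph the cause of a changed value was not tested, except that fewer genes or libraries enter where the alternative leaves them out.

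sh003 against control at day 0 called 1, and 0 with a pseudocount of 0.1, the stricter filter, only the groups compared, the 2 conflicting libraries left out or batch 1 left out, 4 with no filter and 5 with only sh2 libraries of sh003. It called 7 with pseudogenes and batch 1 zeros left out. Pairing libraries by batch gave 49 with the batch block, 0 with batch 1 left out and the block, 51 with block and median-ratio scaling and 39 with block and voom. It gave 67 with block and a pseudocount of 1, 64 with block and stricter filter and 76 with the block with these genes left out too. Leaving out single libraries gave 0 to 23, and 1 to 262 with the block. sh004 at day 0 called 0, and 6 with no filter. With single libraries left out it called 0 to 0, and 0 to 2 with the block.

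sh003 against control at day 7 called 0, and 60 with no filter. Pairing libraries by batch gave 1 with the batch block, block and median-ratio scaling, block and voom, block and a pseudocount of 1 or the block with these genes left out too and 3 with block and stricter filter. The range over single libraries left out was 0 to 8, and 0 to 588 with the block. sh004 at day 7 called 0, and 69 with no filter, 3 with only the groups compared and 1 with only sh2 libraries of sh003. It called 2 with only batch 2 libraries. With libraries paired by batch it called 44 with the batch block, 2 with batch 1 left out and the block, 54 with block and median-ratio scaling and 6 with block and voom. It gave 61 with block and a pseudocount of 1, 43 with block and stricter filter and 42 with the block with these genes left out too. Leaving out single libraries gave 0 to 4, and 2 to 192 with the block. The blocked sh004 set was therefore called in few alternatives without block, and by voom in 6 genes. The cause was not tested.

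The day 7 comparison in controls called 186, and 303 with no filter, 107 with quantile normalization and 1 with only the groups compared. It called 94 with the 2 conflicting libraries left out and 21 with batch 1 left out. Pairing libraries by batch gave 1494 with the batch block, 30 with batch 1 left out and the block, 1537 with block and median-ratio scaling and 1067 with block and voom. It gave 1566 with block and a pseudocount of 1, 1287 with block and stricter filter and 1611 with the block with these genes left out too. With single libraries left out it called 36 to 269, and 116 to 2695 with the block.

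The day 7 comparison with sh003 called 458, and 291 with quantile normalization, 177 with only the groups compared and 192 with the 2 conflicting libraries left out. It called 74 with batch 1 left out and 828 with pseudogenes and batch 1 zeros left out. With libraries paired by batch it called 2779 with the batch block, 88 with batch 1 left out and the block, 2872 with block and median-ratio scaling and 2207 with block and voom. It gave 2729 with block and a pseudocount of 1, 2279 with block and stricter filter and 2818 with the block with these genes left out too. The range over single libraries left out was 124 to 781, and 343 to 4014 with the block.

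The day 7 comparison with sh004 called 74, and 38 with quantile normalization or the 2 conflicting libraries left out, 20 with only the groups compared and 28 with batch 1 left out. Pairing libraries by batch gave 410 with the batch block, 117 with batch 1 left out and the block, 384 with block and median-ratio scaling and 458 with block and voom. It gave 388 with block and a pseudocount of 1, 423 with block and stricter filter and 452 with the block with these genes left out too. Leaving out single libraries gave 15 to 89, and 81 to 1474 with the block. The cause of these changes was not tested.

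The sh003 interaction called 0, and 18 with no filter. With single libraries left out it called 0 to 0, and 0 to 1 with the block. The sh004 interaction called 0, and 19 with no filter. Pairing libraries by batch gave 2 with the batch block, block and median-ratio scaling, block and a pseudocount of 1 or block and stricter filter and 1 with batch 1 left out and the block or the block with these genes left out too. The range over single libraries left out was 0 to 1, and 2 to 7 with the block.

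sh003 against sh004 at day 0 called 1, and 0 with a pseudocount of 0.1, the stricter filter, quantile normalization, only the groups compared, the 2 conflicting libraries left out, only sh2 libraries of sh003, voom or batch 1 left out and 9 with no filter. With libraries paired by batch it called 0 with batch 1 left out and the block or block and voom. Leaving out single libraries gave 0 to 1, and 0 to 3 with the block. The same comparison at day 7 called 4, and 0 with a pseudocount of 0.1, the stricter filter, quantile normalization or batch 1 left out, 8 with a pseudocount of 1 and 45 with no filter. It called 1 with median-ratio scaling, 24 with the 2 conflicting libraries left out, 61 with only sh2 libraries of sh003 and 19 with pseudogenes and batch 1 zeros left out. Pairing libraries by batch gave 139 with the batch block, 136 with block and median-ratio scaling, 55 with block and voom and 167 with block and a pseudocount of 1. It gave 144 with block and stricter filter or the block with these genes left out too. With single libraries left out it called 0 to 339, and 7 to 2268 with the block. The cause was not tested.

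In spheres sh003 against control called 0, and 13 with the deposited RPKM, 3 with the stricter filter and 12 with robust empirical Bayes. The range over single libraries left out was 0 to 120. sh004 against control called 19, and 155 with the deposited RPKM, 0 with no filter or both knockdowns pooled and 49 with the stricter filter. It called 51 with robust empirical Bayes and 3 with voom. Leaving out single libraries gave 0 to 356. sh003 against sh004 called 5865, and 366 with the deposited RPKM, 0 with no filter and 3894 with a required fold of at least 2. With single libraries left out it called 26 to 4795. RARB, higher with sh003 than sh004 in the recomputed values (0.68, adjusted p = 0.0496), reversed to -0.15 with the deposited RPKM (adjusted p = 0.957), whose construction divides most genes by totals other than the library's own. Without single libraries RARB was at 0.54 to 0.83 and did not pass (lowest adjusted p = 0.0746).

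Of 86 list calls 6 held with an estimated correlation, and 6 with the block and an estimated correlation. Those 6 without block are the retinoic acid list in controls, with sh003 and with sh004, the neurotrophic receptor and cholesterol lists with sh004 at day 7 against day 0, and ERK feedback genes with sh003 at day 0. With the block they are the adhesion, ERK feedback and interferon lists with sh003 at day 0, and the retinoic acid, neurotrophic receptor and interferon lists with sh004 at day 7 against day 0. Of 74 monolayer list calls 62 stayed with the block and 1 took the other direction, the cell cycle list with sh004 at day 0 (0.16 to -0.18, adjusted p = 0.278 with the block, 0.992 with an estimated correlation). The overlap of sh003 and sh004 calls at day 7 was 0 and became 1 with the block, HEY1. Knockdown calls measurable in other conditions were 0 without block and 72 with it. The cause was not tested.

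Scaling moved the median log2 change of all genes by over 0.1 in several comparisons. For sh004 against control at day 7 it was -0.148, -0.070 with median-ratio and 0.103 with quantile scaling. For day 7 in controls it was 0.146, 0.068 and -0.026. For sh004 against control spheres it was -0.156 and -0.008, for sh003 against sh004 spheres 0.127 and -0.009, and for sh003 against sh004 at day 0 0.028 and -0.115 with quantile scaling. None of the 86 list medians changed sign. For the KELLY genes and read-outs, 310 of 321 alternative values were the same and 11 moved, and for the sphere read-outs 30 of 36 were the same and 6 moved.

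Depth limits what can be said of genes near 0. The batch 1 libraries held 11.9 to 16.5 M reads, and in the day 7 control libraries VCAM1, LCN2 and C3 lay at or near 0 RPKM, so the log2 changes of such genes depend on the pseudocount.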

Other observations

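The noradrenergic list stood higher with sh003 spheres than control (19 of 23 measured higher, median log2 change 0.42, camera adjusted p = 0.0180, adjusted p = 0.695 with an estimated correlation), with the catecholamine transporter SLC18A1 at 2.52 and GATA2 at 2.48, while in monolayers it stood lower with sh003. The retinoic acid list stood higher with sh003 (10 of 11 measured higher, median log2 change 0.77, camera adjusted p = 0.0180, adjusted p = 0.695 with an estimated correlation) and sh004 spheres (9 of 11 measured higher, median log2 change 1.33, camera adjusted p = 0.00123, adjusted p = 0.518 with an estimated correlation; 0 up and 0 down over all genes, 4 up and 0 down adjusted over the list alone), whose labels name no retinoic acid. The p53 list was higher in sh004 spheres (12 of 14 measured higher, median log2 change 1.13, camera adjusted p = 5.96e-04, adjusted p = 0.714 with an estimated correlation; 0 up and 0 down over all genes, 6 up and 0 down adjusted over the list alone; CDKN1A 2.87, PHLDA3 2.04).

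Genes of the control change from day 0 to day 7 were read in the other tables, ranked among 10000 matched random lists. Without block, those that rose gave a median log2 ratio of 0.22 (above 9947) in sh003 spheres, -0.18 (above 4947) in sh004 spheres and -0.04 (above 217) in KELLY cells with the SOX9 siRNA. Those that fell gave 0.07 (above 8469), -0.08 (above 5845) and 0.08 (above 8926). With the batch block, which calls more genes, those that rose gave 0.15 (above 10000), -0.12 (above 9892) and -0.05 (above 0), and those that fell -0.25 (above 0), -0.14 (above 17) and 0.12 (above 10000). The fallen genes thus differ between fits in sh003 spheres. There the calls with a fold of at least 2 gave 0.32 (above 9982) without and -0.02 (above 8585) with the block. In sh004 spheres the blocked medians changed sign under median-ratio scaling, to 0.03 and 0.01.

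OR2I1P was among the highest values of the sh004 libraries, at 151 and 154 RPKM in spheres, 49.98 in the sh003 sh1 sphere, listed at 0 in the sh003 sh2 sphere, and at 4.79 in the batch 3 control. UBD, its neighbour in the same chromosome region, reached 4.75 in the sh004 sh2 day 7 library and 5.68 in the sh1 sphere. Reads in processed pseudogenes made up 2.41% to 3.22% of the batch 1 libraries, 0.1798% to 0.273% of the other monolayer libraries, and 2.24% and 2.25% of the KELLY libraries.

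In the KELLY pair CRABP2, a retinoic acid carrier, was lower (93.2 to 36.6 RPKM, log2 ratio -1.34), as was the chromogranin family gene CHGB (-0.71), while SLC18A1 was higher (0.98). Several immunoglobulin D segments met the naming rule on 1 read against 5 to 7 reads.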
